A study of Homo sapiens with 6 samples.

How the data were processed

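The libraries for bulk RNA sequencing came from HEK293T cells, an immortalised human embryonic kidney line, transfected with a miR-34a duplex or with the AllStars negative control. Total RNA was collected 18 h after transfection, per the labels. It was purified on columns with a DNase treatment, and libraries were made with Illumina's TruSeq RNA v2 chemistry, which does not mark strand. Each group held 3 libraries, described as biological replicates. The labels call the control an siRNA in the sample descriptions and a miRNA in the series text; it is called the control here.

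The deposited values are raw read counts per Ensembl gene, 1 column per library, which the authors made without normalization. Per the submitters' processing notes, the tools named were STAR 2.7.11a, featureCounts, Subread 2.0.3 and edgeR 3.42.4, with the GRCh38 build. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Every row named a gene, so no unassigned reads entered the totals. Library totals ranged from 24728662 to 36650331 counts. The chi-square statistic per degree of freedom between libraries of the same group lay between 8.39 and 15.98, so no pair of libraries looked like 1 library deposited in duplicate.

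Genes were kept with the edgeR function filterByExpr at its defaults, a minimum count of 10 and a minimum total of 15, which left 17427 of 63140 genes. Counts were scaled by TMM factors, which ranged from 0.981 to 1.016, and fitted with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with group as the only term. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called changed. CPM values are counts scaled by edgeR to the TMM library size. Fold changes are miR-34a over control. The median log2 fold change over all tested genes was -0.004.

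Gene symbols were matched for 58531 of the 63140 identifiers and for 16863 of the tested ones. Coordinates, exons and untranslated regions (UTRs) come from GENCODE release 29 on GRCh38. The plan named MANE Select transcripts first; that release carries no such tags, so the planned fallback was used, the transcript with the longest coding sequence. Sites for miR-34a-5p, UGGCAGUGUCUUAGCUGGUUGU, were searched in the 3′ UTR of that transcript: 8mer CACTGCCA, 7mer-m8 CACTGCC, 7mer-A1 ACTGCCA and 6mer ACTGCC. Each gene took the class of its strongest site. Genes with a 3′ UTR under 50 nt were not classed, which left 12933 classed genes. Site classes were compared with no-site genes by the difference of median log2 fold change, with a 95% interval from 2000 bootstrap resamples of genes, and by camera of limma 3.58.1 with a preset correlation between genes of 0.01 and again with an estimated correlation. The intervals treat genes as independent and leave out the spread between libraries, so they do not measure the uncertainty of the treatment effect. A per-library score for each class, its median centred log2 CPM minus that of the no-site genes, was compared by an exact two-sided permutation test; 3 libraries against 3 cannot give a p below 0.1. Every 7-mer found in at least 100 classed 3′ UTRs was ranked by the t statistic of its presence in a regression of log2 fold change that also held log UTR length and UTR GC content.

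Before the data were examined, 17 gene lists, the site classes, the alternatives and the rule for named genes were fixed. The rule takes the 10 protein-coding genes with the largest fall and the 10 with the largest rise among genes past the threshold with a mean log2 CPM of at least 3 and no overlap between the groups. It adds SIRT1, the 8 published miR-34a targets with the lowest adjusted p, and from each other list up to 3 members past the threshold, or the 2 most expressed where none passed. Lists were tested with camera, adjusted over the 17 lists, with fry and an estimated correlation beside it. Gene names outside this rule were chosen after their values were seen. A gene taken by the rule is not reported here.

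Of the 68 named genes, 19 share exonic sequence with another tested gene, 17 of them with a gene on the opposite strand. Reads from such pairs cannot be told apart without strand. The largest shared parts were 43.2% of the exonic length of CDK4 (with TSPAN31) and 42.3% of ALDOA (with a same-strand read-through gene), and BBOF1, at 5.48 CPM in the control, shares 14.5% with ALDH6A1, at 35.1 CPM.

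The count test was checked on simulated counts drawn from the means of the control libraries and the library sizes of both groups. Of 17053 simulated genes tested, it recovered 89% of the 100 genes changed 1.5-fold and 98% of the 100 changed 2-fold, and 6.03% of its calls were false. Changes were planted only in genes with an average log2 CPM above 1. Recovery of smaller changes, or of genes below that level, was not measured. The alternatives were DESeq2 size factors, library size only, no filter, a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, glmTreat against a 1.2-fold change, an adjusted p under 0.01, offsets for gene GC content (known for 96.1% of tested genes), a replicate block, leaving out each library, another transcript choice, a matched background and a higher expression minimum. Mature miR-34a is too short for these libraries and was not analysed here.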

Results

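The transcriptomes of HEK293T cells transfected with a miR-34a duplex were compared with those of cells transfected with the AllStars control, 18 h after transfection. The series asks how the structure of a miRNA paired with its target bears on repression. miR-34a is a microRNA whose gene is a transcriptional target of p53, and a microRNA guides Argonaute proteins to partly complementary mRNAs, chiefly through its seed near the 5′ end. The control libraries held 24728662, 32322583 and 32849065 counts and the miR-34a libraries 25198898, 29136281 and 36650331 (n = 3 per group). Mitochondrially encoded mRNAs took 2.85 to 4.71% of the counts of a library. The edgeR p-values rest on the spread between these 6 libraries. The host transcript of miR-34a, MIR34AHG, had a log2 fold change of 0.01 ± 0.13 (SE), adjusted p = 0.96 by the edgeR quasi-likelihood test; it is not made from the transfected duplex.

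With miR-34a, 1167 genes fell and 938 rose among 17427 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Most changes were small. The median change was 1.32-fold among the genes that fell and 1.28-fold among those that rose; 277 fell and 202 rose by at least 1.5-fold, and 49 fell and 79 rose by at least 2-fold. The first principal component held 60.9% of the variance and separated the 2 groups. The counts moved by over 1.5 times when single libraries were left out: 604 genes rose and 727 fell without miR-34a replicate 2, 525 rose without control replicate 2 and 606 rose without control replicate 3.

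Among the protein-coding genes past the threshold with a mean log2 CPM of at least 3 and no overlap between the groups, the largest falls were in genes that, apart from MPP2, whose 3′ UTR was not classed, had a 7mer or 8mer site in the 3′ UTR searched. NECTIN1, an immunoglobulin-like cell adhesion molecule, fell from 26.4 ± 1.44 to 7.27 ± 0.113 CPM (SD, n = 3), a log2 fold change of -1.86 ± 0.10 (SE). PPP1R11, an inhibitor of protein phosphatase 1, fell from 39.3 ± 1.35 to 15.1 ± 0.458 CPM, and NUP210, a membrane protein of the nuclear pore, from 307 ± 22.3 to 129 ± 8.18 CPM. SH3GL1, an endophilin that works in endocytosis, fell from 121 ± 4.43 to 55.6 ± 7.07 CPM. MPV17L2, MPP2, DPYSL4 and the transcription factor ZHX2 fell by 1.49, 1.30, 1.24 and 1.14 on the log2 scale. RTL8B had the largest fall of these, with a log2 fold change of -1.98 ± 0.10, but it has the near-identical copies RTL8A (-1.06) and RTL8C (-0.93), and how reads shared by them were counted is not known. The 10 largest falls under these criteria, these 9 and TPD52 (below), had adjusted p-values of 3.9e-08 or lower; RTL8A and RTL8C are not among them.

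Under the same criteria the largest rises were in genes that, apart from RAB36, had no 7mer or 8mer site in the 3′ UTR searched. Only 20.9% of all 12933 classed genes held such a site, so its absence does not set these genes apart. OSCP1 rose from 6.74 ± 0.108 to 21.4 ± 0.907 CPM (SD, n = 3), a log2 fold change of 1.67 ± 0.10 (SE), and CCDC113, found at centriolar satellites, rose from 10.2 ± 1.08 to 25.3 ± 2.75 CPM. IFT88, a core protein of intraflagellar transport, rose from 11.9 ± 0.595 to 25.6 ± 0.730 CPM, and TCTN2, a protein of the ciliary transition zone, from 18.1 ± 1.22 to 38.3 ± 0.806 CPM. The kinases NEK10 and MAPK15 had log2 fold changes of 1.25 and 1.19, the GTPase RAB36 1.26, the metalloproteinase-like LMLN 1.07 and the basal body gene BBOF1 1.30, and FAM227A rose from 12.8 ± 1.04 to 29.3 ± 2.94 CPM. The adjusted p-values of these 10 genes were 1.1e-07 or lower. BBOF1 shares exonic sequence with the more highly expressed ALDH6A1 on the opposite strand, so its value is uncertain.

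**Figure D1:**
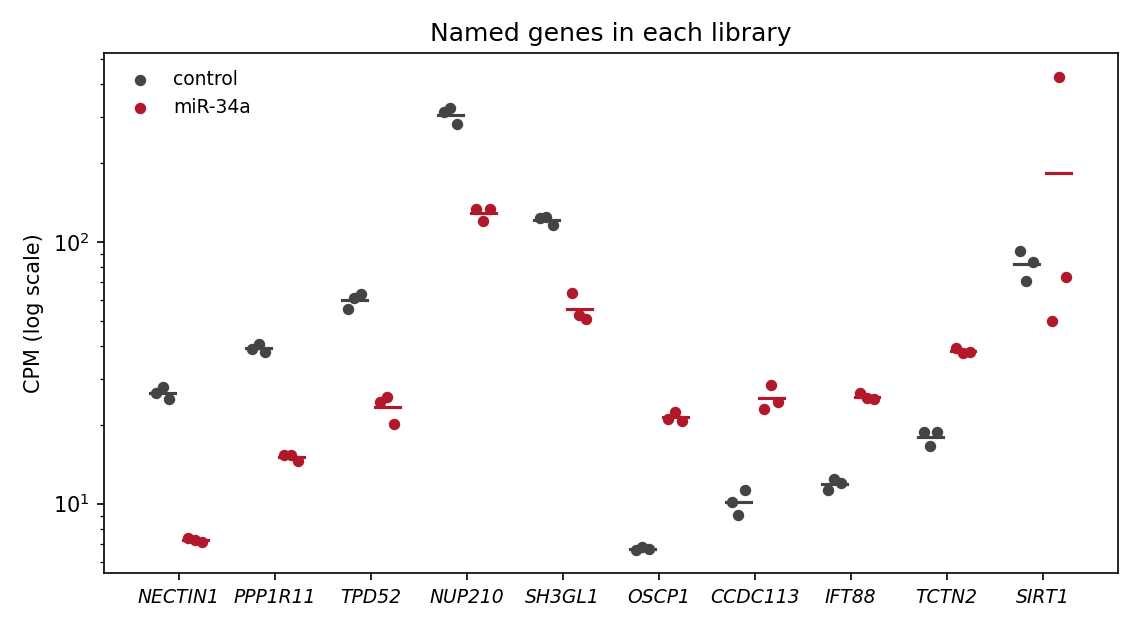
CPM (log axis) of 10 named genes in each of the 6 libraries; points are libraries, grey for control and red for miR-34a, and short lines are group means. The groups do not overlap for the first 9 genes, while SIRT1 stands at 428 CPM in 1 miR-34a library and at 49.7 and 73.3 CPM in the other 2.

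SIRT1, the deacetylase long studied as a miR-34a target, did not pass the test. Its level was 92.4, 71.1 and 83.7 CPM in the control libraries and 49.7, 428 and 73.3 CPM in miR-34a replicates 1, 2 and 3. The log2 fold change was 1.16 ± 0.41 (SE), adjusted p = 0.066 by edgeR. A single library set the sign: without miR-34a replicate 2 the log2 fold change was -0.41, adjusted p = 0.027, while SIRT1 passed upward without control replicate 1 (1.25, adjusted p = 0.013), miR-34a replicate 1 (1.605, adjusted p = 0.0013) or miR-34a replicate 3 (1.54, adjusted p = 0.0011). The 3′ UTR of SIRT1 holds a pair of 7mer-A1 sites in its last exon, on chromosome 10 at 67917484 to 67917490 and at 67918027 to 67918033 (GRCh38, plus strand).

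Genes with a miR-34a seed match in the 3′ UTR were lower than genes without one for 3 of the 4 kinds of match, most so for the 8mer. Of 678 genes with an 8mer, 27.9% fell, against 4.90% of 8941 no-site genes; their median log2 fold change differed from that of the no-site genes by -0.15 (95% interval -0.18 to -0.13; camera adjusted p = 4.5e-16, and adjusted p = 0.0045 with an estimated correlation). Of 1328 genes with a 7mer-m8 as the strongest site, 17.2% fell, with a difference of -0.10 (-0.11 to -0.08; camera adjusted p = 4.3e-07, and adjusted p = 0.0089 with an estimated correlation). Of 696 genes with a 7mer-A1, 15.4% fell, with a difference of -0.04 (-0.06 to -0.02; camera adjusted p = 0.0030, but adjusted p = 0.18 with an estimated correlation). Of 1290 genes with a 6mer, 9.77% fell, with a difference of -0.04 (-0.05 to -0.02) that did not pass (camera adjusted p = 0.074, and adjusted p = 0.18 with an estimated correlation). The exact permutation p of the per-library scores was 0.1, the smallest this design allows, for the 8mer, 7mer-m8 and 7mer-A1 classes and 0.2 for the 6mer.

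Most seed-matched genes did not fall, and 48.2% of the 1088 classed genes that fell had a 7mer or 8mer site. That share was 18.7% among the 10974 classed genes that did not pass the test (Fisher's exact test across genes, which are not independent replicates, p = 2.4e-95). Among the 871 classed genes that rose it was 14.4% (Fisher's exact test, p = 0.0012). Against no-site genes matched on 3′ UTR length and expression the differences grew by over 1.5 times for the 7mer-A1 (-0.09) and the 6mer (-0.08, adjusted p = 0.00014). Without control replicate 1 the 7mer-A1 call was lost (-0.03, adjusted p = 0.073), and the 6mer class passed without control replicate 2 (adjusted p = 0.020) or miR-34a replicate 3 (adjusted p = 0.032).

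**Figure D2:**
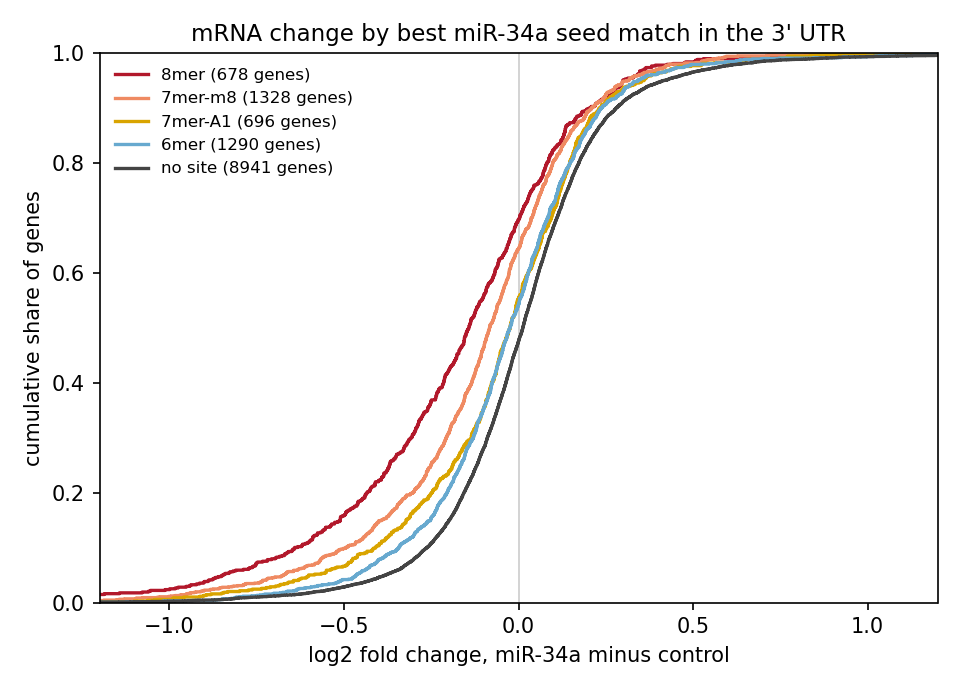
Cumulative share of genes (vertical axis) at or below each log2 fold change, miR-34a minus control (horizontal axis, shown from -1.2 to 1.2), for 5 classes of genes by the strongest miR-34a seed match in the 3′ UTR. The curve of the 678 genes with an 8mer lies farthest to the left, followed by the 1328 with a 7mer-m8, and the 8941 no-site genes lie to the right.

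Among all 15778 7-mers ranked by t statistic, the miR-34a 7mer-m8 match CACTGCC came lowest (t = -18.47) and the 7mer-A1 match ACTGCCA next (t = -16.89). Both had a regression coefficient of -0.13 on the log2 scale at equal UTR length and GC content. This is a ranking across genes, which are not independent replicates.

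None of 7 contrasts between kinds, numbers or places of seed matches passed after adjustment over the family. The genes compared were not matched on UTR length and expression. Such matching moved the 6mer difference from no-site genes from -0.0365 to -0.0805. The unmatched contrasts therefore cannot decide whether these features bear on repression. Genes with an 8mer differed from those with a 7mer-m8 by -0.06 (difference of median log2 fold changes, 95% interval -0.09 to -0.03; camera adjusted p = 0.058). Genes with at least 2 sites of the 7mer or 8mer kind differed from those with 1 site by -0.07 (-0.09 to -0.04; adjusted p = 0.058). The 117 genes whose single site had an upstream match to positions 13 to 16 of miR-34a differed from the 1957 without it by -0.04 (-0.08 to 0.00, adjusted p = 0.33). For genes with no 3′ UTR site, a site in the coding sequence went with a difference of -0.03 (-0.04 to -0.01, adjusted p = 0.17) and a site in the 5′ UTR with 0.01 (-0.02 to 0.03, adjusted p = 0.51). Seed matches of the passenger strand, miR-34a-3p, did not go with lower levels: the 604 genes lay 0.04 higher than the rest, camera p = 0.043, and p = 0.28 with an estimated correlation. This passenger-strand comparison was not matched on UTR length and expression either, so it cannot decide on repression by that strand.

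The positions of the matches in named genes show the range of arrangements. NECTIN1 holds 7 sites of the 7mer or 8mer kind in its last exon, with the 8mer on chromosome 11 at 119662554 to 119662561 (GRCh38, minus strand), 2186 nt after the stop codon. PPP1R11 holds a pair of 8mers 264 and 363 nt after the stop codon, on chromosome 6 at 30069570 to 30069577 and 30069669 to 30069676. The 8mer of TPD52 starts 25 nt after the stop codon, on chromosome 8 at 80038084 to 80038091. TNRC6B, an Argonaute partner, holds 4 such sites, among them an 8mer on chromosome 22 at 40324227 to 40324234, and rose.

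Published miR-34a targets fell as a group. Of 49 tested, 31 fell, none rose and 18 did not pass; adjusted over the list alone, 34 were lower and 1, SIRT1, was higher. The median log2 fold change was -0.54 (camera adjusted p = 1.4e-40, and adjusted p = 0.0031 with an estimated correlation), and 27 of the 31 had a 7mer or 8mer site. TPD52, a gene amplified in several carcinomas, fell from 59.8 ± 4.12 to 23.4 ± 2.91 CPM (SD, n = 3), and SYT1, a calcium sensor of synaptic vesicles, from 12.2 ± 0.268 to 4.70 ± 0.582 CPM. The cyclin-dependent kinases CDK6 and CDK4 fell by 0.90 and 0.96 on the log2 scale, the receptor MET by 0.91, the transcription factor E2F5 by 1.08, the deacetylase HDAC1 by 0.76 and PEA15 by 0.76; these 8 genes had adjusted p-values of 2.8e-08 or lower. CDK4 shares 43.2% of its exonic length with TSPAN31 on the opposite strand and had no site in the 3′ UTR searched. E2F5 shares 16.3% of its exonic length with C8orf59 on the opposite strand. In the control C8orf59 stood at 30.9 CPM and E2F5 at 31.9 CPM, so the value of E2F5 is uncertain. MDM4, with an 8mer, had a log2 fold change of 0.00 ± 0.08 (SE), adjusted p = 0.98, and CTNNB1, with no site, 0.03 ± 0.07, adjusted p = 0.84.

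Cell-cycle genes of the G1/S list fell in part. Of 34 G1/S and DNA replication genes, 8 fell and none rose (adjusted over the list alone, 8 were lower and 1 higher). TK1, which phosphorylates thymidine, fell from 109 ± 12.2 to 50.9 ± 6.85 CPM (SD, n = 3), and the replicative helicase subunits MCM3 and MCM2 fell by 0.64 and 0.44 on the log2 scale. The camera adjusted p was 0.00041, and adjusted p = 0.32 with an estimated correlation. Of 28 G2/M and mitosis genes, 2 fell and 1 rose (the same counts adjusted over the list alone), with FOXM1 at -0.23, PLK1 at -0.21 and KIF23 at 0.22; the list did not pass (camera adjusted p = 0.25). With single libraries left out, FOXM1 lost its call in the fits without control replicate 1 or 3 or miR-34a replicate 1 or 2 (adjusted p = 0.075 to 0.12), PLK1 in each but that without control replicate 2 (0.065 to 0.19) and KIF23 in each but that without control replicate 3 (0.051 to 0.18).

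Some receptors and kinases of 3 signalling lists fell, several of them published miR-34a targets, while most members did not pass. In the Notch list 5 of 25 genes fell and 1 rose (the same counts adjusted over the list alone); the receptors NOTCH1, NOTCH2 and NOTCH3 fell by 0.73, 0.68 and 0.59 on the log2 scale. In the Wnt list 6 of 35 fell and 2 rose (6 and 3 over the list alone); the receptor LGR4 fell by 0.75 and the transcription factor LEF1 by 0.84, while the receptor FZD6 rose, with a log2 fold change of 0.52. In the list of receptor tyrosine kinases and the Ras/MAPK pathway 7 of 30 fell and 3 rose (the same counts adjusted over the list alone), with MET, MAP2K1 and ARAF falling by 0.91, 0.69 and 0.68. Camera adjusted p-values were 0.0042, 0.019 and 0.0049 for these 3 lists, but adjusted p = 0.32, 0.32 and 0.21 with an estimated correlation. With the published targets taken out, the adjusted p-values were 0.26, 0.29 and 0.98, and the Wnt call was also lost without miR-34a replicate 1 (adjusted p = 0.060).

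The p53 target list moved both ways: of 26 genes, 6 fell and 4 rose (6 and 5 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.71). BTG2, an antiproliferative gene, and SESN2, a stress-induced regulator of growth signalling, fell by 0.64 and 0.42 on the log2 scale, while the zinc finger gene ZMAT3 rose, with a log2 fold change of 0.54. CDKN1A, the cell cycle inhibitor p21, had a log2 fold change of -0.28, adjusted p = 0.037.

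Stress and metabolic lists held single strong falls. XBP1, a transcription factor of the unfolded protein response with a 7mer-m8 site, fell from 128 ± 5.96 to 60.6 ± 4.33 CPM (SD, n = 3), and TRIB3 and SESN2 of the same list by 0.55 and 0.42 on the log2 scale; 5 of its 20 genes fell and 1 rose (6 and 1 over the list alone; camera adjusted p = 0.00062, and adjusted p = 0.32 with an estimated correlation). Of 23 genes of cholesterol synthesis and uptake, 5 fell and none rose (7 and 1 adjusted over the list alone). Among them DHCR7, the last enzyme of cholesterol synthesis, fell by 0.74, HMGCS1 by 0.51 and the regulator SREBF2 by 0.44 (camera adjusted p = 0.0029, and adjusted p = 0.32 with an estimated correlation). Of 19 glycolysis genes, 4 fell (5 over the list alone), among them LDHA and TPI1, by 0.37 and 0.33; the list did not pass (camera adjusted p = 0.13), but it did without control replicate 1 (median -0.0996 against -0.041; adjusted p = 0.024) and with no filter (adjusted p = 0.044). ALDOA had a log2 fold change of -0.39, uncertain because of an overlapping gene.

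Factors of the miRNA pathway rose in part, among them genes with miR-34a sites. Of 29 genes, 5 rose and 1 fell (10 and 2 adjusted over the list alone). AGO2, the slicing Argonaute, rose from 126 ± 14.1 to 183 ± 28.3 CPM (SD, n = 3) and TNRC6B from 65.6 ± 3.99 to 89.0 ± 8.23 CPM, while the deadenylase CNOT6 fell from 160 ± 6.46 to 120 ± 5.03 CPM. The camera adjusted p was 0.033, but adjusted p = 0.78 with an estimated correlation, and the call was lost without control replicate 2 (adjusted p = 0.31), control replicate 3 (0.091) or miR-34a replicate 3 (0.10).

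Cytosolic ribosomal protein genes were slightly lower: 14 of 80 fell and none rose (19 lower adjusted over the list alone), with a median log2 fold change of -0.17. RPS3, RPL38 and RPS12 fell by 0.27, 0.27 and 0.29 on the log2 scale. The camera adjusted p of 1.1e-07 became adjusted p = 0.74 with an estimated correlation, and many of these genes have processed pseudogenes that can share reads. RPS3 and RPL38 lost their calls without control replicate 3 or miR-34a replicate 3 (adjusted p = 0.064 to 0.12), and RPS12 also without control replicate 2 or miR-34a replicate 2 (0.061 to 0.10).

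Neither the innate immune list nor the list of stress-induced early genes passed. Over all genes, 2105 of 17427 were called changed, so the small counts below are not particular to these lists. Of 17 tested interferon-stimulated and double-stranded RNA sensing genes, 2 rose (2 over the list alone), among them the kinase EIF2AK2, with a log2 fold change of 0.25; the list did not pass (camera adjusted p = 0.71). EIF2AK2 lost its call without control replicate 2 or 3 or miR-34a replicate 2 or 3 (adjusted p = 0.061 to 0.15). Of 16 immediate early and heat shock genes, 1 fell (1 over the list alone), HSPA1B, with a log2 fold change of -0.43; it shares reads with its near-identical copy HSPA1A and its call was lost with DESeq2 (adjusted p = 0.26) and without control replicate 3 (0.11) or miR-34a replicate 2 (log2 fold change -0.2445, adjusted p = 0.18), so it is uncertain (camera adjusted p = 0.40).

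In 3 lists no gene passed in the main edgeR fit, over all genes or adjusted over the list alone, nor by DESeq2 or limma-voom, and 0, 1 and 0 genes had an unadjusted p under 0.05: 13 mitochondrially encoded mRNAs (camera adjusted p = 0.21; MT-CO1 0.17 and MT-ND4 0.14 on the log2 scale), 23 replication-dependent histone genes (adjusted p = 0.83; H2BC12 -0.14 and H2AC25 -0.14) and 4 markers of other cell types (adjusted p = 0.99; COL1A1 and COL3A1 both -0.09). Of 18 marker genes of blood, stromal, endothelial, epithelial and liver cells, only those 4 were expressed enough to be tested. Of 68 replication-dependent histone genes, only those 23 had enough counts to be tested, so most of that list was not measured. Few counts in these libraries need not mean low expression of histone genes. The list result therefore does not decide whether histone mRNAs changed. In other edgeR fits MT-CO1 passed without control replicate 1 (0.30, adjusted p = 0.019) and with no filter (adjusted p = 0.037), and H2BC12 without control replicate 1 (-0.24, adjusted p = 0.04955). The mitochondrial list depended on single libraries. Its median was 0.0875 in the main fit and 0.2067 without control replicate 1, where it passed (camera adjusted p = 0.0014). Without control replicate 2 the median was -0.0671.

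**Figure D3:**
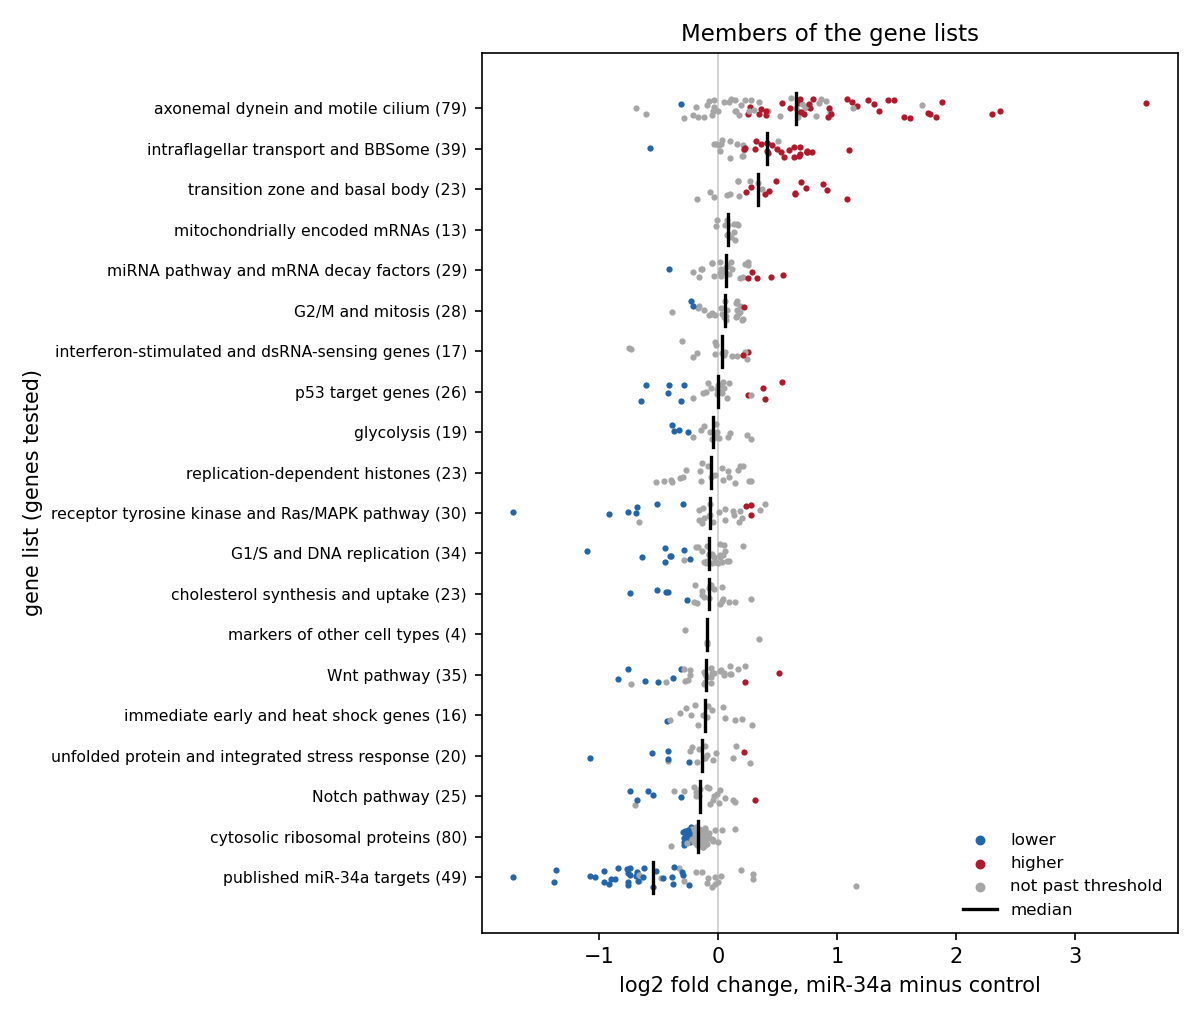
Log2 fold change, miR-34a minus control (horizontal axis), of each tested member of 20 gene lists (vertical axis, with the number of genes tested); blue points fell, red points rose, grey points did not pass, and black bars are medians. The 49 published miR-34a targets have the lowest median, -0.54; the 3 cilium families at the top were chosen after the data were seen.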

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

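Alternatives listed as added after the data were seen are those on the cilium families, FOXJ1, Alu words and single-library gaps. With the normalizations, low-count filters and tests tried, genes that fell numbered 1012 to 1189 and genes that rose 945 to 1079. Of the 2105 changed genes, 2038 were also called with DESeq2, 2036 with limma-voom and 1934 with library size only. With GC offsets 1048 fell and 690 rose, and 1407 were kept. Stricter criteria gave fewer genes by construction: 669 fell and 464 rose at an adjusted p under 0.01, and 314 and 190 against a 1.2-fold change. Leaving out single libraries gave 727 to 1394 genes that fell and 525 to 1287 that rose.

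The replicate numbers do not pair the samples. Correlations of same-numbered deviations were -0.21, -0.05 and -0.26, and 0 of 6 libraries matched their own number best. With a replicate block 1023 genes fell and 807 rose, 1782 of the 2105 kept, and FOXM1, KIF23, PLK1 and RPS3 were not called (adjusted p = 0.056 to 0.11); with the block and GC offsets 831 fell and 529 rose. The cause was not tested.

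The 8mer and 7mer-m8 classes kept their direction and call in all 15 alternatives run on them. GC offsets, the DESeq2 test and limma-voom were not run on the site classes. With single libraries left out, the 8mer and 7mer-m8 differences ranged from -0.18 to -0.13 and from -0.11 to -0.08. The 7mer-A1 class (-0.0316 to -0.0499 with single libraries left out) lost its call without control replicate 1 and with an estimated correlation (-0.0364, adjusted p = 0.18). The 6mer class (-0.0242 to -0.0405) passed with a matched background (-0.0805). SIRT1 ranged from -0.4121 without miR-34a replicate 2, where it reversed, to 1.6046 without miR-34a replicate 1. It passed upward without control replicate 1 (1.2523), miR-34a replicate 1 or miR-34a replicate 3 (1.5407). It also passed with no filter (1.17, edgeR adjusted p = 1.3e-53), but that p-value is not reliable. The same SIRT1 counts gave adjusted p = 0.066 in the main edgeR fit, and adjusted p = 0.49 with both DESeq2 and limma-voom. The cause of these shifts was not tested. Over all single genes followed, 47 values in alternatives lost the call and 853 kept their side of the threshold. The 3 cilium families and the published targets kept direction and call in all alternatives run on them. The mitochondrial list passed upward in 5 alternatives, up to a median of 0.21 without control replicate 1, but its median was -0.0671 without control replicate 2 and -0.0633 without miR-34a replicate 2.

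Depth limits genes near the floor: 17427 of the 34377 genes with any count were tested.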

Other observations

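Tests chosen only after the result was seen are those of the cilium families, of Alu words and of SIRT1, and the gene names in this part.

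Genes of the cilium rose together. Of 39 genes of intraflagellar transport and the BBSome, the machinery that carries cargo along the cilium, 24 rose and 1 fell, with a median log2 fold change of 0.41. IFT88, IFT81, the motor subunits KIF3A and KIF3B and DYNC2LI1 had log2 fold changes of 1.10, 0.68, 0.60, 0.64 and 0.79, while the motor gene KIF17 had -0.57. Of 23 genes of the transition zone and basal body, 12 rose and none fell, among them TCTN1 (0.88) and TMEM67 (0.74). Of 79 tested genes of axonemal dyneins and motile cilia, 36 rose and 1 fell, with a median of 0.65; DNAI3 rose from 3.83 ± 1.11 to 13.1 ± 2.25 CPM and DNAH7 from 0.999 ± 0.185 to 3.69 ± 0.826 CPM (SD, n = 3). Camera with an estimated correlation gave adjusted p = 0.0010, 0.0010 and 0.0060 for the 3 families. Together 72 of their 141 genes rose, 51.1% against 5.0% of other tested genes.

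Genes known to act on cilium formation moved in both directions. CCP110, a centriolar cap protein that holds back cilium assembly, rose, with a log2 fold change of 0.57 ± 0.07 (SE, edgeR adjusted p = 1.8e-06). MYB, TP73 and MCIDAS, regulators of multiciliated cells that each have a 7mer-m8 site, fell by 0.97, 0.39 and 0.61 on the log2 scale. RFX1 (0.25, edgeR adjusted p = 0.076), RFX2 (-0.10, edgeR adjusted p = 0.61) and RFX3 (0.29, edgeR adjusted p = 0.14) did not pass. RFX1 has a 7mer-m8 site and RFX3 an 8mer, and neither fell. RFX5 and RFX7 rose, with log2 fold changes of 0.24 (edgeR adjusted p = 0.018) and 0.28 (edgeR adjusted p = 0.049).

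The rise of the cilium families was weighed against GC content, 5 words of 3′ UTRs and their known transcription factors. With GC offsets the median over the 141 genes was 0.39, against 0.42 without. The 88 genes without any of the 5 7-mers with the highest t statistics had a median of 0.41. Both values argue against GC content and these 5 words as the whole cause. Other words that cilium 3′ UTRs may share were not tested. Of 6 known transcription factors tested, 1 was higher, FOXJ1, with counts of 0, 10 and 0 in the control libraries and 11, 18 and 18 with miR-34a. Its log2 fold change was 2.18 in the main fit (edgeR adjusted p = 0.040). The call was lost in 6 of 11 alternatives, with values of 1.58 to 2.28 there (edgeR adjusted p = 0.056 to 0.19). The 5 that kept it gave 2.19 to 6.94, the highest without control replicate 2, where the remaining controls held 0 counts. More FOXJ1 mRNA as the source therefore stays open. An indirect effect of miR-34a on cilium genes may be at work, as a hypothesis found in these data; the reagents or the state of the cells were not separated from the miRNA, since each group had 1 treatment.

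SIRT1 was the only gene more than 2-fold above the other 5 libraries in miR-34a replicate 2, where it had 12501 counts, against 1250 to 2713 elsewhere. Its neighbours HERC4 (53.8 CPM there, 44.0 to 52.0 elsewhere) and DNAJC12 (17.4 CPM there) showed no such rise. The 8mer score of that library, -0.0953 (log2), lay with the other miR-34a libraries (-0.0913 and -0.0482) and below the controls (0.0524 to 0.106), and no further gene stood out there, which argues against a mislabelled library. SIRT1 sequence from outside the cells, such as a plasmid or amplified product, could give such a value: 0 other genes rose with it. Counts per gene do not show where reads lie within SIRT1, so this and a rise of the endogenous mRNA in that culture cannot be told apart, and no biological explanation was tested.

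The lower level of 8mer genes was weighed against other properties of their 3′ UTRs. Against no-site genes matched on UTR length and expression the difference grew, from -0.1545 to -0.2208, which argues against length and expression as its cause. The rank of CACTGCC among all 7-mers by t statistic, 1 from the lowest in a regression with UTR GC content, argues against base composition. Direct repression by miR-34a through its seed is consistent with both values and was not tested against other routes.

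With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 2105 genes by edgeR and the highest other 0; 1 split of 10, the real one, gave as many. For the 8mer class the real difference was 0.1545 in size and the highest other 0.0955 (1 of 10). The fixed lists passed by camera with the preset correlation 9 times in the real split and 8 times in the highest other (1 of 10 reached 9). Each other split passed 2 to 8 lists while calling 0 genes. A list call with the preset correlation alone is therefore weak evidence of an effect of the treatment.

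A hypothesis was that genes without miR-34a sites rise because the added miRNA competes with endogenous miRNAs for Argonaute. Of all 7-mers, GCACTTT, the seed match of the miR-17 family, had the highest t statistic in the regression (7.67, coefficient 0.05), but the words of the other 3 families tested ranked lower: miR-19 (t = 2.68), miR-25/92 (t = 2.04) and miR-15/16 (t = -0.46). Genes with no miR-34a site and matches to at least 3 of the 4 families lay 0.1492 above genes with none (235 and 5697 genes; limma camera adjusted p = 1.9e-10 over 16 such tests, adjusted p = 0.16 with an estimated correlation), as competition predicts. By single family and without Alu words, genes with a miR-25/92 match lay 0.0665 higher (357 genes; adjusted p = 0.0089, adjusted p = 0.22 with an estimated correlation) and genes with a miR-19 match 0.0537 higher (495 genes; adjusted p = 0.0096, adjusted p = 0.16 with an estimated correlation), while the miR-15/16 family did not pass (0.0177, 826 genes; adjusted p = 0.42). Matched on UTR length and expression, genes with at least 3 families lay 0.0933 above genes with none, against 0.1492 unmatched (158 genes each, camera adjusted p = 0.0039, and adjusted p = 0.25 with an estimated correlation). With the preset correlation this met the criterion fixed beforehand against UTR length and expression as the cause. With an estimated correlation the matched difference did not pass, so UTR length and expression may still account for part or all of it. Alu elements, whose sequence holds GCACTTT, are a further candidate source: without Alu words the genes with GCACTTT lay 0.071 higher (adjusted p = 0.0039, adjusted p = 0.16 with an estimated correlation), but 0.04 after matching (adjusted p = 0.28, adjusted p = 0.25 with an estimated correlation), so Alu elements and miR-17 family sites cannot be told apart at this size.

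Non-canonical pairing was also tested, in 2 hypotheses. Genes with a seed match that holds 1 G:U wobble and no canonical site differed by 0.0113 from genes with neither (2063 genes, camera adjusted p = 0.42). These genes were not matched on UTR length and expression, and such matching moved the 6mer difference from -0.0365 to -0.0805. The unmatched value therefore cannot decide on repression through wobble sites. In the regression with UTR length and GC content, the wobble words had t statistics of -1.81 to -0.09. The 197 genes with the wobble at position 7 alone differed by -0.07 (camera adjusted p = 0.030, and adjusted p = 0.36 with an estimated correlation). Genes with a match around 1 bulged base differed by -0.0381 (285 genes; adjusted p = 0.18, adjusted p = 0.16 with an estimated correlation), which leaves a small effect of such sites possible.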
